A study of Zea mays with 45 samples.

How the data were processed

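The deposited tables hold 1 log2 ratio per spot and array, for 45 arrays of maize leaf RNA. Per the labels, each array held a pair of RNAs labelled in 2 channels, and the design text of the series describes analysis of variance models fitted by the authors to base-2 log intensities with terms for line, array, treatment, dye and spot, followed by a false discovery rate, and a threshold on weak spots. Whether the deposited log2 ratios passed through these models, which RNA stands on top of the ratio and how the authors scaled the channels are not given in the sources used here. Medians of the deposited arrays range from -0.47 to 0.61. Blank spots were taken as missing. The labels give a UV-B exposure of 8 h for the arrays of Confite and Mishca against W23.

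Samples were grouped by the labels into comparison, line and treatment. W23 and the W23 stock with b and pl alleles were treated as 1 line. The titles of the Cacahuacintle arrays give 3 without and 1 with UV-B. For Arrocillo and Conico they give as many with as without, and whether 1 of the 3 is mislabelled is not known. Columns were compared before use: 8 equalled another column up to a constant within an SD of 0.01 and were counted once, and 1 column, the third W23 array under solar UV-B, differed from the mean of the other W23 arrays by an SD of 0.032 and was left out. Results were tested within a table only, so the landraces were fitted as 2 sets, 3 on 1 table and 2 on the other. A mean over all 5 landraces in 1 fit, as first planned, was not possible.

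Spots of a probe, 3 in most cases, were averaged (the median SD within a probe was 0.03 and 0.04 in the 2 tables) and each array was centred on its median. Probes measured on at least 75% of the arrays and on at least 1 array of each group were kept. A linear model per probe held a coefficient for each line, or landrace and treatment, and a channel term shared by the arrays of a comparison. It was fitted with limma 3.58.1 in R 4.3.3 by least squares over the arrays that measured the probe, with moderated variances, two-sided tests and Benjamini-Hochberg adjustment, and a probe was called at an adjusted p under 0.05. Residual degrees of freedom were 2 for solar UV-B, 1 for supplemental UV-B, 5 for Arrocillo, Cacahuacintle and Conico, and 2 for Confite and Mishca. In the supplemental comparison 5140 probes passed the filter and 4744 kept a residual degree of freedom and were tested. Lines with 1 distinct array borrow the spread of the others. A column deposited under both channel orders was given a channel code of 0, so that the channel term removed nothing from it. Giving it the order of its first or of its second label was an alternative.

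Gene names came from the platform annotation of the probes, which is old, and from the symbols of a current maize reference annotation (Zm-B73-REFERENCE-NAM-5.0), used for names only. On the arrays 401 and 406 probes were listed, 399 and 404 with 1 gene and 2 in each table with several, which were not named, and 5239 and 5354 probes had no name here. They cover 329 genes, of which 314 are in the reference. cDNA probes can hybridise with close family members, so values of aquaporins, tubulins and other families are uncertain at the level of 1 gene. No coordinates were used.

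The genes named in the text follow a rule: per mean and side, the 10 named genes with the largest log2 ratio among called probes whose lines all have the same sign, up to 4 members per gene list with the largest moderated statistic among those called, phenylalanine ammonia-lyase, 8 other flavonoid genes, the light-harvesting and Rubisco small subunit genes whatever their values, and per line the 2 largest on each side. A gene with several probes is named by its probe with the smallest p, and other probes are given where they lie on the other side. The groups, the tests, the rule, 22 gene lists and most alternatives were fixed before the data were examined. The lists were extended by hand to the gene names on the arrays after the names, but not the values, had been seen: 206 genes received a name and 175 a list. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry as alternatives.

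Position on the array was taken from the numbering of the spots, split into 16 sections of consecutive spots. Centring each section on its median, on every array, was added after the data were examined, as were the fits on lines with distinct arrays of both channel orders, the fit with the repeated columns counted as arrays, those with the repeated columns given either channel order, the fit with the third W23 array kept and the reading in which ratios follow the channel order. Other alternatives were values without centring, scaling to equal spread, no channel term, other filters, array weights, no moderation, probes averaged by gene, line means as replicates, the replicate number as a block, and leaving out each array and each line.

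The model fit and the calls were tested on simulated ratios with 200 changed probes. The noise was independent with the fitted spread, and each changed probe moved alike in all lines. No trends over the array were simulated, and columns with a channel code of 0 held no channel part. Averaging of spots, centring, naming and the list tests were not covered. At a log2 change of 0.5 and of 1 all of the changed probes were recovered in the solar, the supplemental and the 3-landrace fits (100.0% each), and 31.0% and 95% in the fit of Confite and Mishca. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.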

Results

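Spotted cDNA arrays read in 2 colours measured RNA from leaves of 6 maize lines, the inbred W23 and the landraces Arrocillo, Cacahuacintle, Confite, Conico and Mishca, in a study of solar ultraviolet-B (UV-B) radiation and high-altitude maize. Plants grew outdoors under plastic that passed or removed UV-B, or under UV-B lamps. Each array set a pair of RNA samples against each other and gave their log2 ratio. In the deposited data 13 columns compared leaves under solar UV-B with leaves kept from UV-B, 12 compared supplemental with solar UV-B, and 20 compared a landrace with W23 under the same treatment. The 45 columns fell into 22 groups. Of these columns, 8 repeated another column, up to a constant, under the opposite channel label, and 1 was the mean of the other W23 solar columns (SD of the difference 0.032). The 36 distinct columns were used: 9 for solar UV-B, 8 for supplemental UV-B, 12 for Arrocillo, Cacahuacintle and Conico against W23, and 7 for Confite and Mishca against W23. The 12 landrace arrays formed a table of their own, with 5760 probes, and the others shared a table of 5640 probes. Array medians ranged from -0.47 to 0.61 and array SDs from 0.27 to 0.66, and between 4% and 72.6% of the spots of an array were blank. The number of arrays limits the precision.

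The labels name the RNA in each channel but not which of the pair stands on top of the ratio. Values are therefore given as lying on the positive or the negative side of the deposited ratio, as sizes and counts, with no statement of which sample held more RNA. In the table of Arrocillo, Cacahuacintle and Conico, arrays of 1 group with opposite channel order correlated positively across probes in 5 of 5 groups (mean r per group from 0.06 to 0.43). In the other table this held in 2 of 3 solar groups (Mishca at -0.24), in 0 of 2 supplemental groups (-0.11 and -0.07) and in 1 of 3 groups of Confite and Mishca against W23, so that the side was often not kept when the channels were exchanged. With sections of each array (runs of consecutively numbered spots) centred, it held in 3 of 3, 2 of 2 and 1 of 3 of these groups. Probes are not independent replicates. Nothing in the labels says that arrays of a group hold RNA of separate plants, and opposite channel orders of a group may be the same RNA hybridised again. The p-values therefore measure the spread between arrays of a group after the channel term, not the spread between lines. In the UV-B comparisons that spread comes only from lines with distinct arrays of both channel orders, 3 for solar and 2 for supplemental UV-B.

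The first comparison asked how leaves of the landraces differ from those of W23. In Arrocillo, Cacahuacintle and Conico the largest named difference was on the negative side and belonged to thi2, an enzyme of thiamine synthesis, with a mean log2 ratio of -1.70 (SE 0.11, n = 12 arrays, 3.25-fold, adjusted p = 2.2e-07). Its other probes stood at -1.07 (called), -0.12 and -0.09 (neither called). After thi2 came LOC541942 (-1.40, SE 0.09), the invertase gene ivr2 (-0.99, SE 0.07, with its other probe called at 0.51), the chitinase gene chn1 (-0.94, SE 0.09) and the oxophytodienoate reductase gene opr6 (-0.84, SE 0.10). The light-harvesting protein gene lhcb5 (-0.80, SE 0.09) and the ferredoxin-thioredoxin reductase gene ftr1 (-0.72, SE 0.07) lay on the same side. On the positive side the largest named difference was that of LOC542313, a phosphohexose isomerase, at 1.02 (SE 0.10, 2.03-fold, adjusted p = 7.7e-06). LOC100037792 and LOC542531 followed at 0.69 each, and the chaperone gene hsp101 (0.58, SE 0.07), the beta-glucosidase gene glu1 (0.55, SE 0.08) and the Rubisco activase gene rca1 (0.52, SE 0.07) were among the 10 largest. Each of these genes had the same sign in all 3 landraces, which was a condition for the 10 largest. Of the 80 called named genes 79 met it.

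Over all named genes 80 of 310 passed. By list, 6 of the 10 measured genes of defence and wound response passed the test, 5 on the negative side and 1 on the positive side. The negative ones included chn1, opr6 and the cystatin gene psei2 (-0.60, SE 0.06), and the positive one was glu1, whose other probe stood at -0.25. Over probes, 7 of 13 were called over all probes tested and 8 of 13 adjusted over the list alone. Antioxidant and detoxification genes passed in 4 of 15 cases (4 adjusted over the list alone), each on the negative side: the glutathione S-transferase gene GST39 (-0.72, SE 0.09), the catalase gene cat1 (-0.41, SE 0.08), the ferritin gene fer1 (-0.39, SE 0.08) and the superoxide dismutase gene Sod4A (-0.34, SE 0.06). Carbon fixation and C4 cycle genes passed in 4 of 9 cases (5 adjusted over the list alone). Of these, rca1 and the malic enzyme genes me4 (0.46, SE 0.08) and me2 (0.27, SE 0.06) were positive, and pdrp1 (-0.36, SE 0.09; -0.21 without the Cacahuacintle array with UV-B, adjusted p = 0.129) was negative. The Rubisco small subunit gene ssu1 stood at 0.08 and did not pass (adjusted p = 0.363).

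Of 9 probes of photosynthetic light reactions 5 were called (6 adjusted over the list alone), with lhcb5, ftr1 and psaN (-0.23, SE 0.07) on the negative side and pgr5 (0.38, SE 0.11; 0.22 without the second Arrocillo array with UV-B, adjusted p = 0.0391) among the positive ones. The light-harvesting gene Cab-m7 stood at -0.23 and did not pass (adjusted p = 0.0584), but passed with sections centred (-0.16, adjusted p = 0.0415), with scaling, with array weights and without either of 2 single arrays. Heat shock and chaperone probes were called in 5 of 11 cases (6 adjusted over the list alone), 4 of them negative. The negative ones belonged to the protein disulfide isomerases PDIL1-1 (-0.68, SE 0.07) and PDIL1-2 (-0.47, SE 0.07), and the positive one to hsp101. Chromatin genes passed in 3 of 18 cases (3 adjusted over the list alone): the DNA methyltransferase gene met2 (0.37, SE 0.11) and the histone deacetylase gene Hda1 (0.27, SE 0.07) were positive, and the Polycomb group gene fie2 (-0.26, SE 0.07) was negative. Among seed and pollen markers, the storage globulin genes globulin-1 (0.48, SE 0.06, with its other probe at -0.31) and Globulin-2 (0.24, SE 0.07; 0.14 with array sections centred, adjusted p = 0.0807) passed on the positive side (3 of 9 probes over all probes, 3 adjusted over the list alone). Of the flavonoid pathway, 0 of the 8 genes fixed beforehand were on the arrays under those symbols. The phenylalanine ammonia-lyase gene PAL1 stood at 0.02 (adjusted p = 0.897).

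In all, 1368 of 5353 probes passed in this mean over 3 landraces, 719 on the positive and 649 on the negative side (limma, Benjamini-Hochberg adjusted p under 0.05), and 80 of 310 named genes passed, 37 positive and 43 negative. Arrocillo alone gave 439 called probes, Cacahuacintle 475 and Conico 285. In Arrocillo the largest named values were LOC542313 (1.29) and LOC541942 (-1.28), in Cacahuacintle LOC542531 (0.88) and thi2 (-2.02), and in Conico LOC542313 (0.96) and LOC541942 (-1.48). A test of the difference between the landraces called 6 probes, none of them named. The difference between arrays with and without UV-B, averaged over these landraces, called 0 probes in limma (257 at an unadjusted p under 0.05). It takes the UV-B labels of the Cacahuacintle arrays as given, and whether 1 of them is wrong is not known. Without centring of the arrays 1049 probes were called, 31.3% of them positive against 52.6% with centring, and without the channel term 885 were called. Without the Cacahuacintle arrays 786 were called and without Conico 783. Of 53 called genes named by the rule, 12 lost their call without at least 1 single array, psaN, pgr5, met2 and Globulin-2 among them, and without Conico met2 stood at 0.10 (adjusted p = 0.669).

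Before the field comparisons, a property of the arrays has to be stated. Spots in their numbered order fell into 8 equal runs, and called probes of the UV-B comparisons were spread unevenly over them. In the comparison of solar with no UV-B the second run held 241 positive and 16 negative calls and the fifth held 20 and 214. In the comparison of supplemental with solar UV-B the first held 15 and 246 and the seventh held 180 and 19. With each run halved into 2, the 16 sections accounted for 12.7% to 54.8% of an array's variance in the solar comparison (median 20.0%), 17.9% to 49.8% in the supplemental one (median 32.4%) and 5.8% to 19.3% in Arrocillo, Cacahuacintle and Conico (median 13.6%). Leading UV-B values are therefore followed by the value after every section of every array was centred on its median, a setting added after the data were examined.

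**Figure D1:**
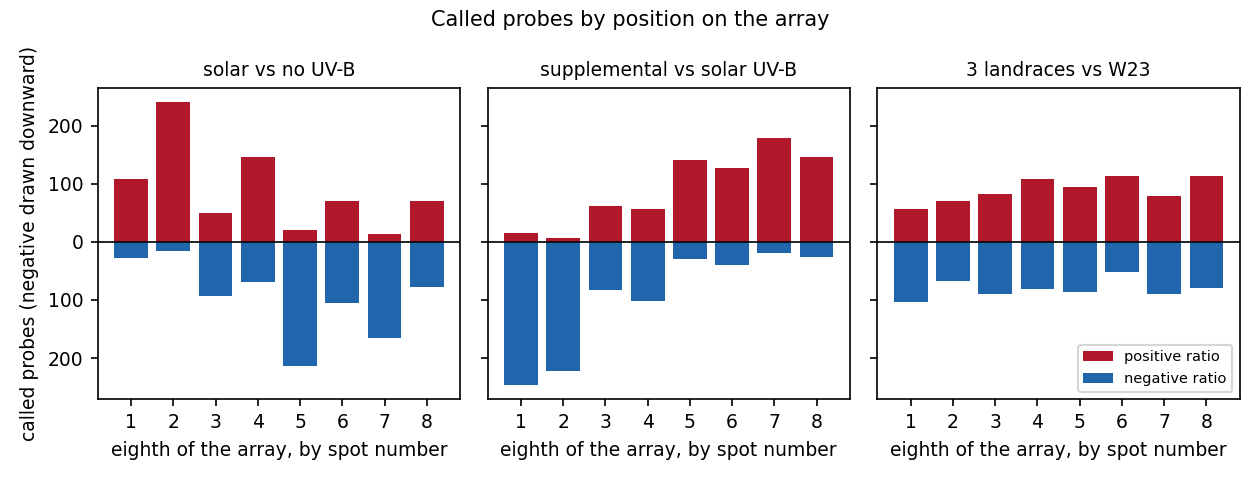
Number of called probes on the positive side (red) and the negative side (blue, drawn downward) of the deposited ratio, in each eighth of the array by spot number, for the 2 UV-B comparisons and for 3 landraces against W23. The eighths range from 241 positive calls in the second eighth of the solar comparison to 246 negative calls in the first eighth of the supplemental one.

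The second comparison asked what solar UV-B changes in leaves. The largest named value on the positive side was that of LOC100125656, with a mean log2 ratio over 6 lines of 0.84 (SE 0.07, n = 9 arrays, 1.79-fold, adjusted p = 0.00474) and 0.71 with sections centred. The oxophytodienoate reductase gene opr6 (0.65, SE 0.07; 0.67 with sections centred), the alpha-tubulin gene tua4 (0.61, SE 0.04; 0.43), the aquaporin gene pip1-2 (0.52, SE 0.07; 0.54) and asr1, a gene of abscisic acid and stress responses (0.50, SE 0.07; 0.31), lay on the same side. The photosystem II gene psbs1, which encodes the subunit of non-photochemical quenching, was also positive (0.55, SE 0.07, and 0.45 with sections centred). So was the photosystem II gene lhcb5 (0.45, SE 0.06, and 0.35 with sections centred). These 7 genes had the same sign in all 6 lines, which was a condition for their choice among the largest values. Of the 100 called named genes 35 met it. On the negative side stood globulin-1 (-0.46, SE 0.04, adjusted p = 0.0055; -0.37 with sections centred, but -0.12 in the 3 lines with distinct arrays of both channel orders, adjusted p = 0.118), the nucleosome assembly gene nfa104 (-0.35, SE 0.04; -0.32) and the chromatin assembly gene nfc102 (-0.25, SE 0.04; -0.16).

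Of 59 called genes named by the rule, 47 were called with sections centred. A set of 17 was called under 4 settings: all lines, all lines with sections centred, the 3 lines with distinct arrays of both channel orders, and these 3 lines with sections centred. Of these 11 were positive: LOC100125656, opr6, tua4, psbs1, pip1-2, asr1, lhcb5, grf1, the peroxiredoxin gene PER1, the ribosomal protein gene rpl29 and Sod4A. The 6 negative ones were the pollen expansin gene EXPB9, PIP1-3, nfa104, nfc102, the acetyl-CoA carboxylase gene ACC1 (its other probe at -0.00 over all lines, not called) and NIP2-3. The 4 settings share arrays, so they are not independent of each other. The others named by the rule lost their call under at least 1 of these settings, and called genes outside the rule were not compared over all 4. Without 1 array at a time, 27 of the 59 lost their call at least once, among them ACC1 without the Confite array (-0.14, adjusted p = 0.0889), Sod4A without either Conico array (0.053 and 0.0527) and NIP2-3 without the Arrocillo array (-0.10, adjusted p = 0.117). In the 3 lines with both channel orders and sections centred, LOC100125656 stood at 0.82 (adjusted p = 0.0092), opr6 at 0.51 (0.0187), psbs1 at 0.32 (0.0178), lhcb5 at 0.19 (0.0319), ACC1 at -0.36 (0.0093) and nfa104 at -0.31 (0.0177). PAL1 stood at -0.22 (SE 0.05, adjusted p = 0.0245) but at -0.11 with sections centred (adjusted p = 0.0876), at -0.29 in the 3 lines with both channel orders (0.0404) and at -0.21 there with sections centred (0.0426). The Rubisco small subunit gene ssu1 stood at 0.08 (adjusted p = 0.14; 0.10 with sections centred, 0.0469, and also called without the first W23 array).

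Over all named genes 100 of 284 passed for solar UV-B. By list, 5 of 9 probes of photosynthetic light reactions were called (5 adjusted over the list alone), each on the positive side. Beside psbs1 and lhcb5 they included Cab-m7 (0.30, SE 0.06), which stood at 0.12 with sections centred and at -0.03 in the lines with both channel orders and sections centred. Genes of defence and wound response passed in 3 of 9 cases (3 probes adjusted over the list alone), each positive: opr6, the pathogenesis-related gene pr5 (0.42, SE 0.07; 0.24 with sections centred) and the allene oxide synthase gene aos1 (0.33, SE 0.07; 0.15). In the lines with both channel orders and sections centred pr5 stood at 0.07 (adjusted p = 0.341) and aos1 at 0.01 (0.93). Antioxidant and detoxification genes passed in 4 of 13 cases (5 adjusted over the list alone). PER1 (0.25, SE 0.04) and Sod4A (0.22, SE 0.05) kept their calls with sections centred. GST39 (0.16, SE 0.04; -0.02 with sections centred) and fer1 (-0.15, SE 0.04; -0.05) did not. Chromatin genes passed in 4 of 17 cases (4 adjusted over the list alone), with nfa104, nfc102 and the methyl-CpG-binding gene mbd113 (-0.19, SE 0.04) negative and the histone acetyltransferase gene hac106 positive (0.26, SE 0.05; 0.13 with sections centred), whose call was lost there. Of the genes of other cell types, the mesophyll marker pdk1, pyruvate orthophosphate dikinase, was positive (0.30, SE 0.07; 0.28 with sections centred, 0.18 without the Arrocillo array, adjusted p = 0.123, and 0.11 in the lines with both channel orders and sections centred, adjusted p = 0.222), and the seed and pollen markers globulin-1 and EXPB9 were negative (2 of 6 probes, 2 adjusted over the list alone).

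In all, 1485 of 4239 probes passed in the mean over 6 lines (limma, Benjamini-Hochberg adjusted p under 0.05), 718 positive and 767 negative, and 100 of 284 named genes, 59 positive and 41 negative. With sections centred 1653 probes were called, 785 positive and 868 negative, and 1105 of the 1485 were called with the same sign. In single lines 1011 probes were called in W23, 304 in Cacahuacintle, 281 in Confite, 198 in Conico, 23 in Arrocillo and 1 in Mishca. The largest named values were LOC100125656 (1.22) and PIP1-3 (-1.02) in W23, pip1-2 (1.09) and globulin-1 (-1.10) in Cacahuacintle, LOC100125656 (1.16) and LOC542531 (-1.40) in Confite, and asr1 (0.83) and Mcysp (-0.82) in Conico. The test of the difference between lines called 1 probe (1751 at an unadjusted p under 0.05), 821 with sections centred and 3107 and 3225 without either W23 array, so that the lines are not shown to be alike. Arrocillo, Cacahuacintle and Confite had 1 distinct array each, deposited under both channel orders. The order of these arrays is unknown, so no channel part was removed from them, and they correlated with the part that turned with the channels in the other lines at 0.52 to 0.66. Given the order of their first label 1130 probes were called, 1115 of them among the 1485, and given that of their second label 1717, with 1448 among the 1485. Only 11 probes were called without the channel term, 0 with line means as the replicates (934 at an unadjusted p under 0.05) and 652 without centring of the arrays, 77.1% of them positive against 48.4% with centring. The count was 653 in the 3 lines with both channel orders, 993 there with sections centred, 897 without Confite, 809 and 814 without either Conico array, 2567 and 2437 without either W23 array, and 2649 without W23.

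The third comparison asked what UV-B beyond the solar level changes. The largest named value on the positive side was LOC541658, at 0.72 over 6 lines (SE 0.08, n = 8 arrays, 1.64-fold, adjusted p = 3.4e-05; 0.71 with sections centred). It stood at 2.12 in Mishca, at 0.43 without the Mishca array (adjusted p = 0.00369) and at 0.30 in Confite and Conico (adjusted p = 0.0983). The chromatin assembly gene nfc102 (0.46, SE 0.08; 0.42 with sections centred), hir1, a gene of the hypersensitive response (0.42, SE 0.08; 0.26), the phototropin gene phot1 (0.40, SE 0.07; 0.47) and ftr1 (0.35, SE 0.08; 0.21) were on the same side. On the negative side the glutamine synthetase genes GLN6 (-0.56, SE 0.08, adjusted p = 1.8e-04; -0.36 with sections centred) and gs2 (-0.37, SE 0.07; -0.30) stood beside LOC542168 (-0.53, SE 0.07; -0.34) and the chaperone gene hsp101 (-0.35, SE 0.07; -0.28). GLN6, gs2 and LOC542168 were negative in all 6 lines, and LOC541658, nfc102 and hir1 positive in all 6. The same sign in all lines was a condition for their choice among the largest values. Of the 104 called named genes 40 met it.

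Of 56 called genes named by the rule, 39 were called with sections centred, and 6 under all 4 settings, here with the 2 lines of both channel orders, Confite and Conico. The 2 positive ones were ftr1, which stood at 0.58 in those 2 lines with sections centred (adjusted p = 1.1e-05), and hir1 (0.37, adjusted p = 0.00167). The other probe of hir1 stood at 0.06 over all lines and was not called. The 4 negative ones were GLN6 (-0.59, adjusted p = 1.0e-05), LOC542168 (-0.46, adjusted p = 1.3e-04), hsp101 (-0.33, adjusted p = 0.00324) and PER1 (-0.32, adjusted p = 0.00385). Confite and Conico had 1 distinct array of each channel order per line, which left 1 residual degree of freedom. The p-values in these 2 lines therefore rest mostly on the moderated variances. The 4 settings share arrays, so they are not independent of each other. The others named by the rule lost their call under at least 1 of these settings, and called genes outside the rule were not compared over all 4. Without the Mishca array 26 of the 56 lost their call and 24 moved by over 1.5 times: hsp101 stood at -0.12 (adjusted p = 0.304), PER1 at -0.13 (0.288), psei3 at 0.23 (0.0734), psei1 at 0.25 (0.0669), hir1 at 0.27 (0.0392), gs2 at -0.24 (0.0467), mlip15 at 0.30 (0.0365), sus2 at 0.31 (0.0231), gsh2 at 0.30 (0.0197) and Hda1 at 0.27 (0.0346). Without the Arrocillo array phot1 stood at 0.23 (0.0384). Other genes with large means were near 0 in those 2 lines with sections centred: the low-temperature bZIP gene mlip15 was at 0.56 over all lines and 0.02 there, the sucrose synthase gene sus2 at 0.55 and 0.09, the glutathione synthetase gene gsh2 at 0.52 and 0.05, and the cystatin gene psei3 at 0.41 and 0.00. The photosystem gene psbs1 stood at -0.31 over all lines and at 0.24 there, so its side was not kept. PAL1 stood at 0.21 (adjusted p = 0.0442) and at 0.05 with sections centred (adjusted p = 0.505).

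Over all named genes 104 of 303 passed for supplemental UV-B. By list, transcription factors were called in 6 of 10 cases (6 adjusted over the list alone), 4 of them positive, mlip15 and dbf1 (0.51, SE 0.08; 0.35 with sections centred, but 0.05 in Confite and Conico with sections centred, adjusted p = 0.689) among these. Defence and wound response probes were called in 6 of 12 cases (7 adjusted over the list alone), with hir1, psei3 and psei1 (0.38, SE 0.09; 0.23 with sections centred, 0.14 in Confite and Conico with sections centred, adjusted p = 0.232) among the positive ones and glu1 negative (-0.39, SE 0.08; -0.19 with sections centred). Kinase and phosphatase genes passed in 4 of 9 cases (5 of 10 probes, 6 adjusted over the list alone), with phot1 the largest. Chromatin genes passed in 6 of 18 cases (6 adjusted over the list alone), 3 on each side, with nfc102 and Hda1 (0.45, SE 0.08; 0.43 with sections centred) positive and hac106 (-0.38, SE 0.08; -0.19) negative. The other probe of Hda1 stood at 0.00 and was not called. Phenylpropanoid and flavonoid genes passed in 4 of 5 cases (4 adjusted over the list alone), 3 of them negative, and 1 of the 4 calls was kept with sections centred. Without the Mishca array the 4 calls were lost, with PAL1 at 0.13, 4CL at -0.24, pOMT1 at -0.04 and cncr1 at -0.17. Heat shock and chaperone genes passed in 4 of 9 cases (4 adjusted over the list alone), 3 of them negative, and hsp101 was the 1 kept with sections centred. The light-harvesting genes lhcb5 (-0.10, adjusted p = 0.37) and Cab-m7 (-0.19, adjusted p = 0.055) did not pass, and ssu1 stood at -0.14 (adjusted p = 0.171), but Cab-m7 passed without the Mishca array and with arrays scaled to equal spread, and ssu1 passed with sections centred (-0.26, adjusted p = 0.00345).

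**Figure D2:**
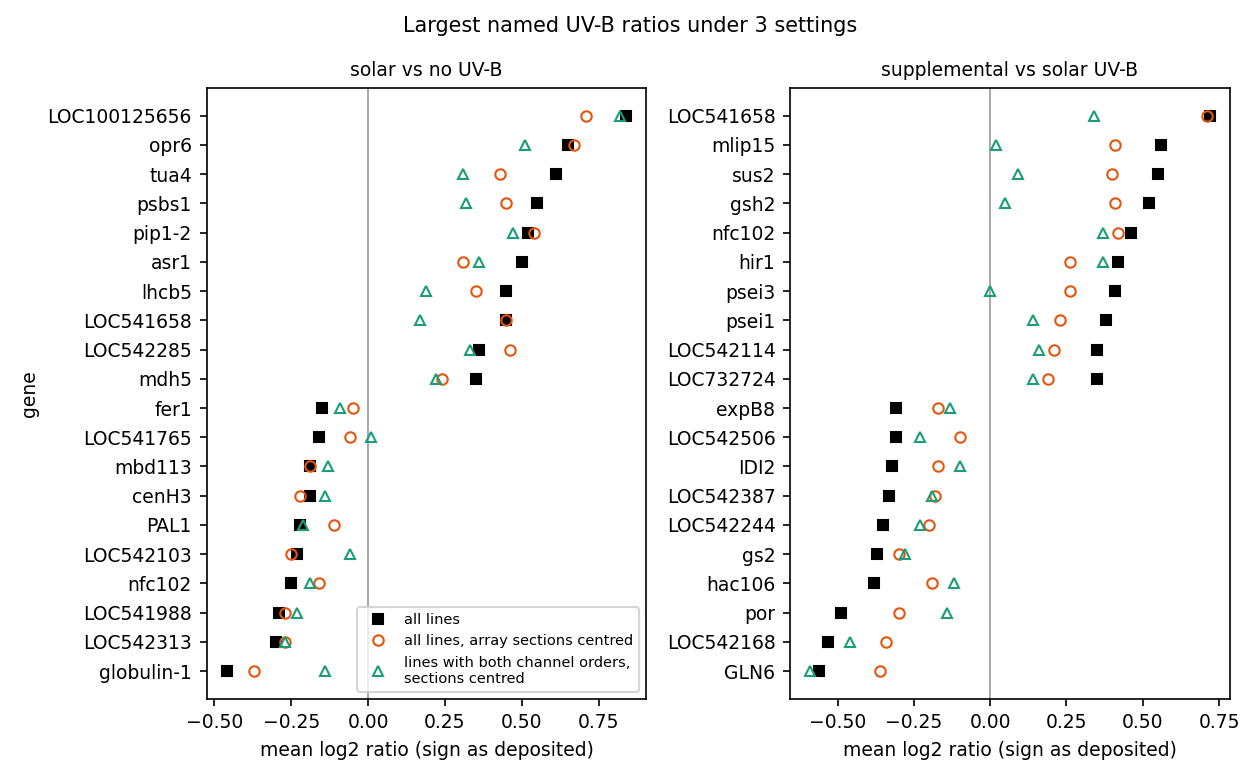
Mean log2 ratio for the 10 named genes with the largest called value on each side in the solar and the supplemental UV-B comparisons: all lines (black squares), all lines with the sections of each array centred (orange circles), and the lines with both channel orders with sections centred (green triangles). In the supplemental comparison mlip15 moves from 0.56 to 0.02 between the first and the last of these settings, while GLN6 stands at -0.56 and -0.59.

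In all, 1504 of 4744 probes passed in the mean over 6 lines (limma, Benjamini-Hochberg adjusted p under 0.05), 736 positive and 768 negative, and 104 of 303 named genes, 54 positive and 50 negative. With sections centred 1675 were called, and 1004 of the 1504 were called with the same sign. The test of the difference between lines called 1168 probes, LOC542531 (adjusted p = 1.0e-05), LOC541911 (1.7e-04) and LOC100125656 (4.1e-04) among them, but 206 without the Mishca array, 5 with arrays scaled to equal spread and 1 without the channel term, so the count rests largely on that array. Mishca alone gave 1970 called probes, Conico 201, Confite 101, Arrocillo 36, W23 24 and Cacahuacintle 10. In Mishca, measured on 1 distinct array, LOC541658 stood at 2.12, mlip15 at 1.81, LOC542531 at -2.19 and hsp101 at -1.51. With arrays scaled to equal spread most calls of single lines were lost, and the Mishca array had the widest spread of all arrays (SD 0.66). This array correlated with the part that turned with the channels in Confite and Conico at -0.61, and at -0.72 with sections centred. The arrays of W23, Arrocillo and Cacahuacintle stood at 0.36 to 0.60, and at -0.01 to 0.26 with sections centred. In Conico ftr1 stood at 0.91 and LOC100125656 at -1.26, in Confite LOC100101527 at 0.98 and LOC542531 at -1.21, and in Arrocillo phot1 at 1.24 and LOC100037792 at -0.99. The count moved with Mishca and with the channel term: 733 probes were called without Mishca, 0 without the channel term, 0 with line means as the replicates (974 at an unadjusted p under 0.05), 184 in Confite and Conico alone and 1000 there with sections centred. W23, Mishca, Arrocillo and Cacahuacintle had 1 distinct array each, deposited under both channel orders, from which no channel part was removed. Given the order of their first label 1426 probes were called and given that of their second 1405, of which 887 and 856 were among the 1504. Without centring of the arrays 62.0% of the calls were positive, against 48.9% with it, and 879 probes were called with arrays scaled to equal spread.

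The remaining landraces, Confite and Mishca, differed from W23 at 34 of 2089 probes, 18 positive and 16 negative (limma, 153 at an unadjusted p under 0.05), and 0 of 146 named genes passed. The light-harvesting gene Cab-m7 stood at -0.14 (SE 0.18) and ssu1 at 0.19 (SE 0.18), both with an adjusted p of 0.996. Confite alone gave 20 called probes and Mishca 6, and within the Confite arrays with UV-B, psei2, named after its value was seen, was called at -1.43 (adjusted p = 0.00624). The difference between these landraces called 0 probes (47 at an unadjusted p under 0.05), and that between arrays with and without UV-B called 2. These 7 arrays were blank on up to 72.6% of their spots, and the simulated recovery was 31.0% at a log2 change of 0.5 and 95% at 1. With sections centred 0 probes were called (168 at an unadjusted p under 0.05), while each of the 34 kept its sign and their median size stayed at 0.73, and without centring 16% of 25 calls were positive against 52.9% with it, and without 1 array the count ranged from 6 to 58.

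The solar and supplemental comparisons both hold leaves under solar UV-B, and the labels do not say whether these are the same leaves. Of 4148 probes tested in both, 576 were called in both. Which sample stands on top of the ratio is not known for either comparison, so the sides below are those of the deposited signs and would change places if the signs of 1 comparison were turned. As deposited, 65 probes were positive in both (104.5 for independent lists), 80 negative in both (125.3), 198 positive and then negative (114.3), and 233 negative and then positive (114.6), or 145 on the same side and 431 on opposite sides. With the signs of 1 comparison turned it is 431 on the same side and 145 on opposite sides. With sections centred 623 probes were called in both: 104 positive in both (144.8 for independent lists), 162 negative in both (139.8), 119 positive and then negative (127.4), and 238 negative and then positive (158.8). The excess of calls positive and then negative and the deficit of calls negative in both were thus not kept. Among named genes PER1 was positive and then negative under the 4 settings, though its supplemental call was lost without the Mishca array. Over all lines nfc102 was negative and then positive, and its supplemental call was lost in Confite and Conico (0.32, adjusted p = 0.0767) but not there with sections centred (0.37, adjusted p = 0.00144). LOC541658 and Sod4A were positive in both over all lines, but not called in both in the lines with both channel orders and sections centred (solar LOC541658 at 0.17, adjusted p = 0.167, and supplemental Sod4A at 0.17, adjusted p = 0.109). PIP1-3, negative and then positive over all lines, and psbs1, positive and then negative, changed side there in the supplemental comparison, to -0.22 (adjusted p = 0.0408) and 0.24 (adjusted p = 0.0325). The values correlated across probes at -0.24 as deposited and 0.24 with 1 comparison turned, and at -0.07 and 0.07 with sections centred. In 20 simulations with shared solar leaves, no effect and the same sample order in both comparisons the correlation was -0.42 (-0.46 to -0.38), the covariance -0.001 against -0.009 observed, and limma called 0 probes in both against 576 observed. The simulated noise was independent, without trends over the array or channel parts, so few calls are made by construction. The 0 therefore does not say whether shared leaves could give the 576. Whether the comparisons hold the same solar leaves is not known and these could not be split. The share of the observed calls that comes from shared leaves was therefore not measured.

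As whole lists, 0 of 61 tests of gene lists against all other probes passed (camera with a preset correlation, Benjamini-Hochberg over the lists of a comparison). The lowest adjusted p was 0.0571 for Arrocillo, Cacahuacintle and Conico, reached by defence and wound response and by antioxidant and detoxification, with carbon fixation at 0.0632. With an estimated correlation the adjusted p was 0.499, 0.391 and 0.391 for these lists. The lowest adjusted p was 0.126 for solar UV-B (photosynthetic light reactions, adjusted p = 0.824 with an estimated correlation), 0.481 for supplemental UV-B and 0.605 for Confite and Mishca. When lists were matched by the symbols fixed beforehand alone, the 3 probes of carbon fixation and the C4 cycle passed in Arrocillo, Cacahuacintle and Conico (adjusted p = 0.0495), but not with an estimated correlation (adjusted p = 0.146). The fry test, which asks whether the members of a list move on balance to 1 side, called 12 of the 61. Lists with 1 or 2 measured genes were described as genes: the centromeric histone gene cenH3 (-0.19, SE 0.05) and the flap endonuclease gene FEN1 of DNA repair (-0.24, SE 0.05) were negative in the solar comparison, but FEN1 stood at -0.08 without the Cacahuacintle array (adjusted p = 0.299) and cenH3 lost its call without either Mishca or either Conico array (adjusted p from 0.0542 to 0.123).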

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

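The tests of array position, those of the channel effect and of the W23 RNA in Arrocillo, Cacahuacintle and Conico, and that of the repeated columns were chosen only after the results they bear on had been seen.

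Limma's test of the difference between lines in their UV-B response called 1 probe for solar UV-B (1751 at an unadjusted p under 0.05; 821 with array sections centred, 3107 and 3225 without either W23 array) and 1168 probes for supplemental UV-B (206 without the Mishca array, 5 with arrays scaled to equal spread). The supplemental count thus rests largely on 1 array, and neither count is stable. The single solar probe is unnamed, and its lines ranged from -1.26 to 1.27. The 1168 hold the named genes LOC542531 (adjusted p = 1.0e-05), LOC541911 (1.7e-04), LOC100125656 (4.1e-04), LOC541658 (6.2e-04) and thi2 (0.00138). The 3 landraces Arrocillo, Cacahuacintle and Conico differed from each other at 6 probes, all unnamed. Whether the difference from W23 changed with UV-B was called at 9 probes in Arrocillo, at 1 in Cacahuacintle (adjusted p = 0.00212), at 2 in the mean of Confite and Mishca, at 1 in Confite and at 2 in Mishca, none of them named. On 1 side of these UV-B differences Cacahuacintle had 1 array, that with UV-B, and Mishca 1 distinct array, that without. Whether the titles of all Cacahuacintle arrays name the right treatment is not known. No explanation was tested for these counts. Probes in these small counts were chosen after their values were seen.

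The first pattern is the large number of calls in the UV-B comparisons. In 1 of 100 sign patterns of the solar arrays, the deposited one, as many probes were called as the 1485 observed, with 472 the highest of the others. In the supplemental comparison it was also 1 of 100, with 1504 against 840. The channel code of an array was kept when its sign was turned, so a channel part alone favours the deposited signs. Chance is therefore not excluded by this test. The test also does not address trends over the array that several arrays share. After each of 16 sections was centred, 74.4% of the solar calls and 66.8% of the supplemental ones were still made with the same sign. This argues against the levels of these sections as the whole cause, while the remaining calls may owe to them. Trends within a section were not removed, so position at a finer scale stays open. An effect of UV-B stays open, as does a technical repeat of the same RNA on arrays of a line, which would make the p-values too small.

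The second pattern is the part of the ratios that turned when the channels were exchanged, taken from the difference of arrays of opposite order. A channel (dye) effect of the probes would give the same turning part, up to its sign, in each comparison on this array design, and the mean turning parts correlated across probes at 0.43 for solar UV-B with Confite and Mishca against W23, at -0.79 for solar with supplemental UV-B and at -0.59 for supplemental UV-B with Confite and Mishca. With sections centred these were 0.09, -0.58 and -0.40, so that section levels have what they need for the first and are argued against as the whole cause of the others. Trends within a section were not removed. A dye effect, which needs all 3 and a turned numerator in the supplemental comparison, cannot be told apart from the rest. If the ratios instead followed the channels, the solar leaves would stand on opposite sides of the UV-B comparisons, which would also make their turning parts opposed, and the steady parts would hold the dye effect, but these correlated at -0.12, -0.13 and -0.08, which leaves that reading open. With sections centred, opposite channel orders correlated positively in 11 of 13 groups, against 8 without.

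The third pattern is the set of calls common to Arrocillo, Cacahuacintle and Conico. In 1 of 100 sign patterns were as many probes called as the 1368 observed, with 452 the highest of the others. The channel codes were kept here too, so chance is not excluded by this test. With sections centred 94.4% of the 1368 were still called with the same sign. This argues against section levels as the whole cause, while trends within a section were not removed. The means of the opposite channel orders correlated across probes at 0.35. A channel effect alone would make them opposed if the ratios keep the sample order, but alike if the ratios follow the channels. That order is not known, so the value leaves a channel effect open. W23 stood on every array, and the landraces differed from each other at 6 of 5353 probes (0.11%), so that a difference of the W23 RNA alone cannot be told apart from one shared by the landraces. A biological difference between the landraces and W23 stays open as a hypothesis.

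The channel codes were again kept for Confite and Mishca, so the sign test does not exclude chance. There 1 of 64 sign patterns gave as many calls as the 34 observed, with 18 the highest of the others. With sections centred 0.0% of these probes were called by limma, though each of the 34 kept its sign and had an unadjusted p under 0.05, with a median size of 0.73 before (median SE 0.18) and 0.73 after (0.16). The calls ended because the prior degrees of freedom of the moderated variances fell from infinite, where every probe has 1 common variance, to 4.80, so that the calls rest on that common variance and position cannot be told apart from other sources of the values. For the difference with against without UV-B in Arrocillo, Cacahuacintle and Conico, 0 probes were called in limma (257 at an unadjusted p under 0.05). Every split gives at least 0 calls, so that the 100 of 100 splits that did so say nothing about chance. The highest split gave 218. That split placed 4 arrays with the landrace in channel 1 among its 5 arrays called with UV-B, and 5 arrays with W23 in channel 1 among its 7 others, and its labels were the true ones in 3 of the 5 and 5 of the 7. That split was picked as the highest, and 4 of the splits drawn had over 10 called probes. Whether its count exceeds what chance gives was not tested, and no structure of these arrays was identified.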

How the results depend on the processing

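The fits with the sections of an array centred, on lines with both channel orders, with repeated columns counted as arrays or given either channel order, with the third W23 array kept (1757 calls for solar UV-B against 1485) and with ratios read in channel order were chosen after the data were seen, and the others before. Across all alternatives 161 values of the counts stayed within 1.5 times of the reported count and 142 did not. Of the values of single named genes, 3889 kept their side and stayed on the same side of the threshold, 1060 kept their side and lost the call, 12 gained a call and 34 changed side. The cause of the changes was not tested, except where fewer arrays or lines enter by construction and for the calls of Confite and Mishca with sections centred, which ended with the common variance. The comparison of Arrocillo, Cacahuacintle and Conico with W23 moved less than the UV-B comparisons. In its mean 1298 of 1443 values of named genes kept side and call, against 1153 of 1596 for solar and 776 of 1180 for supplemental UV-B. Under every alternative run 30 of its 56 named genes did so, against 0 of 60 and 0 of 59. Line means as replicates gave 0 calls in both UV-B comparisons, so for called genes these 0 counts were fixed by that setting. The weak spots of the Confite and Mishca arrays, blank on up to 72.6%, limit what those arrays can show.

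For solar UV-B the mean over lines (1485 called) gave 652 without centring, 11 without the channel term, 2290 with array weights, 2 without moderation, 897 without Confite, 2649 without W23, 653 in lines with both channel orders (374 shared with the 1485) and 0 in limma both with line means as replicates (934 at an unadjusted p under 0.05) and in channel order (742). Leaving out an array gave 809 to 2567. The difference between lines (1) gave 0 without centring (1338 at an unadjusted p under 0.05), 426 with scaling, 0 without the channel term (372), 3370 with array weights, 2 without moderation, 821 with sections centred and 1 to 3225 without an array. The single lines (1818 in sum) gave 8 without the channel term, 9707 with array weights, 8 without moderation, 2955 with sections centred and 1043 without the second Conico array to 9749 without the second W23 array.

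For supplemental UV-B the mean (1504) gave 879 with scaling, 733 without Mishca, 184 in lines with both channel orders, 1000 there with sections centred and 2814 with repeated columns counted. It gave 0 without the channel term (824 at an unadjusted p under 0.05), without moderation (427), with line means as replicates (974) and in channel order (1088). Leaving out an array gave 733 to 1485. The difference between lines (1168) gave 3305 without centring, 5 with scaling, 1 without the channel term, 0 without moderation (327) and 206 without Mishca to 1292. The single lines (2342) gave 4842 without centring, 41 with scaling, 2 without the channel term, 0 without moderation, 3887 with sections centred and 380 without Mishca to 2332. Fits without 1 Confite or Conico array, or without either line, left no residual degree of freedom and were not run.

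For Arrocillo, Cacahuacintle and Conico the mean (1368) gave 885 without the channel term, 892 without moderation, 786 without Cacahuacintle, 783 without Conico and 955 to 1548 without an array. The difference between landraces (6) gave 3 without centring, 18 with scaling, 2 without the channel term, 199 with array weights, 0 without moderation (277 at an unadjusted p under 0.05), 1 without Cacahuacintle and 0 to 8 without an array. The single landraces (1199) gave 746 without centring, 495 without the channel term, 3876 with array weights, 295 without moderation, 647 without Cacahuacintle, 2178 with sections centred and 748 (without the first Arrocillo array without UV-B) to 1622 without an array. The difference with against without UV-B (0) gave 2 with scaling, 3 with array weights, 1 without Arrocillo, 1 without Conico, 7 with sections centred and 0 to 10 without an array, 10 being the value without the Cacahuacintle array with UV-B.

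For Confite and Mishca the mean (34) gave 9 without the channel term, 5 for probes on every array, 55 with array weights, 0 without moderation (103 at an unadjusted p under 0.05), 120 with repeated columns counted, 66 with line means as replicates, 4 in channel order, 0 with sections centred (168) and 6 to 58 without an array. The lowest count came without the first Confite array without UV-B and the highest without the second Mishca array with UV-B. The difference between them (0) gave 1 with array weights and 0 to 26 without an array. The single landraces (26) gave 8 with scaling, 5 without the channel term, 4 for probes on every array, 122 with array weights, 0 without moderation, 0 with sections centred and 0 to 100 without an array. The difference with against without UV-B (2) gave 1 without centring, 4 with array weights, 0 without the channel term, for probes on every array, without moderation, with sections centred and with line means as replicates, and 0 to 3 without an array.

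The replicate number as a block gave 1253 calls in the mean of Arrocillo, Cacahuacintle and Conico, 1 for their difference, 21 in the mean of Confite and Mishca, 17 for these landraces singly and 0 for their UV-B difference (28 at an unadjusted p under 0.05). No label ties arrays of the same number to a shared day or plant. In the UV-B comparisons the replicate number equals the channel order in every pair, so no block could be fitted beside the channel term.

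Probes called in both UV-B comparisons rose from 576 to 922 at an adjusted p under 0.10. Of gene lists, 0 of 61 passed, 12 with fry. By fixed symbols 1 of 8 passed, 0 with an estimated correlation and 3 with fry.

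Genes that changed side in lines with both channel orders were, for solar UV-B, TIP4-1 (-0.01), L-FNRI (-0.05), Mcysp (-0.11) and dxs2 (-0.02), and for supplemental UV-B, PIP1-3 (-0.16), EXPB9 (-0.15), lhcb5 (0.19), Cab-m7 (0.15), L-FNRI (0.01), cncr1 (0.03) and psbs1 (0.27). With sections centred in those lines they were Cab-m7 (-0.03), me4 (-0.03), Mcysp (-0.08) and LOC541765 (0.01) for solar UV-B, and PIP1-3 (-0.22), asn1 (-0.03), EXPB9 (-0.22), lhcb5 (0.17), Cab-m7 (0.12), cncr1 (0.06) and psbs1 (0.24) for supplemental UV-B. With sections centred in all lines they were GST39 (-0.02, solar) and lhcb5 (0.05, supplemental). PAL1 in Arrocillo, Cacahuacintle and Conico (0.02) changed side without centring (-0.04), without Cacahuacintle (-0.02) and without Conico (-0.01), and ranged from -0.07 to 0.09 without single arrays. Cab-m7 in Confite and Mishca (-0.14) stood at 0.01 and 0.02 without the Mishca array without UV-B and without the second Confite array without UV-B, and at -0.29 without the first.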

Other observations

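The tests of the repeated columns were chosen after they had been found, and the gene groups here were formed from gene names and not tested as lists.

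Called water channel genes lay on both sides for solar UV-B, for supplemental UV-B and in Arrocillo, Cacahuacintle and Conico, and 0 of 7 were called in Confite and Mishca. Of 9 aquaporin genes measured for solar UV-B, 4 were called and kept with sections centred: pip1-2 (0.52) and TIP4-1 (0.26) were positive and PIP1-3 (-0.37) and NIP2-3 (-0.15) negative, though TIP4-1 stood at -0.01 in the lines with both channel orders. For supplemental UV-B 5 of 10 were called and 2 of them kept with sections centred, PIP1-1 at -0.51 and PIP1-3 at 0.38, the latter turning to -0.16 in the lines with both channel orders and to -0.22 there with sections centred. Without the Mishca array PIP1-3 stood at 0.19 and lost its call. Among Arrocillo, Cacahuacintle and Conico 3 of 11 were called, TIP4-1 at -0.83, PIP1-1 at 0.37 and TIP2-1 at 0.25, the last losing its call without single arrays (adjusted p up to 0.1). Genes of nitrogen assimilation were called in 3 of 8 cases for solar UV-B, with the glutamine synthetase gene gln4 (0.28) and the nitrite reductase gene NIR (0.22) positive and the asparagine synthetase gene asn1 (-0.29) negative. In the lines with both channel orders these calls were lost, with gln4 at 0.09 (0.18 over all lines without the Cacahuacintle array), NIR at 0.15 and asn1 at -0.12 (adjusted p of 0.292, 0.0725 and 0.145). For supplemental UV-B 3 of 8 were called, with the glutamine synthetase genes GLN6 (-0.56) and gs2 (-0.37) negative and asn1 (0.31) positive, its other probe standing at -0.01. In Confite and Conico asn1 stood at 0.00, and without the Mishca array at 0.19 (adjusted p = 0.106). The nitrate reductase gene NNR1 stood at -0.23 in Arrocillo, Cacahuacintle and Conico and lost its call without single arrays (adjusted p up to 0.0821).

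Genes of starch and sucrose metabolism were called in 4 of 9 cases in Arrocillo, Cacahuacintle and Conico, and each call was kept with sections centred. The ADP-glucose pyrophosphorylase subunit gene sh2 (0.47) and the sucrose phosphate phosphatase gene spp1 (0.46) were positive and the invertase gene ivr2 (-0.99) was negative, with its other probe at 0.51. For solar UV-B 4 of 7 were called, with Agp2 (0.28) positive and the starch synthase gene du1 (-0.28) negative, but in the lines with both channel orders and sections centred they stood at 0.05 and -0.07 and were not called (adjusted p of 0.339 and 0.216), and for supplemental UV-B 0 of 9 were called. Some genes stood out in more than 1 comparison: opr6 and lhcb5 were negative in these landraces (-0.84 and -0.80) and positive for solar UV-B (0.65 and 0.45), and globulin-1 was positive in the landraces (0.48) and negative for solar UV-B (-0.46, but -0.12 and not called in the lines with both channel orders). The numerators of these ratios are unknown, so the sides cannot be set against each other across comparisons.

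The 8 columns that repeat another column carry the opposite channel label. If each were a plain average of arrays of both orders it would hold no turning part. An average made after the sign of 1 array was turned would keep it. The 3 solar columns correlated across probes with the mean turning part of the solar comparison at 0.52 or more, and at 0.44 to 0.61 with array sections centred, which argues against a plain average for these. Trends within a section were not removed, and an average with 1 sign turned stays open. The 4 supplemental columns correlated with the turning part of their comparison at 0.36 (W23), 0.60 (Arrocillo), 0.42 (Cacahuacintle) and -0.61 (Mishca), and with sections centred at -0.01, 0.26, 0.07 and -0.72. Trends over the array enter these values, and for the set of supplemental columns an average cannot be told apart from a single array. Nor can it for the Mishca column against W23, which stood at -0.10 (0.01 with sections centred). How these columns came to be deposited under both labels was not tested further.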
